A study of Bacillus subtilis subsp. subtilis str. 168 with 5 samples.

How the data were processed

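RNA was sequenced from 5 cultures of *Bacillus subtilis* 168, a Gram-positive laboratory strain. Each culture was 1 group with 1 sample, given DMSO (the solvent control) or 1 of 4 plant alkaloids, berberine, boldine, bulbocapnine or roemerine, at 75 mg/L for 1 h. Per the labels' protocols, cells were grown in nutrient broth at 37 °C, stabilised with RNAprotect and broken mechanically, and RNA was purified on RNeasy columns. The molecule label reads polyA RNA, and how ribosomal RNA was treated is not given in the sources used here. The groups were taken from the labels. No file of the DMSO sample was used.

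The deposited files were 4 tables of the authors' own comparisons, 1 per alkaloid, each with 4332 features. Per the submitters' processing notes, R 3.3.3 and DESeq2 were used. The aligner, counter and genome build are not given in the sources used here, so no coordinates are printed. Per the file headers, each table held the mean normalized count over the libraries compared (a signal that is never negative), a log2 fold change with its standard error, the Wald statistic (a score equal to the deposited fold change over its error), a p-value and an adjusted p-value. Missing values were marked by a text code and kept missing. Gene names were used as the files give them; 3578 of the 4332 names matched symbols of the RefSeq annotation of assembly ASM904v1, and 59 features were numbered miscellaneous RNAs. Some genes stand under older names, so list members under other names count as not measured.

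The mean normalized counts that the authors deposited were resolved into whole counts. In every table each mean was a whole multiple of 1 step plus a whole multiple of another, and 4 times the product of the 2 steps was 1, as it is for 1 library per condition and the median-ratio size factors of 2 libraries. The 4 tables were then solved together for 1 library common to all. All 4332 genes had a single solution under 1 of the 16 ways of choosing the common library's step, and the next best way solved 279 genes. The common library is the DMSO library, because the design compares each alkaloid with it. Tables taken alone solved 4189 genes for berberine, 4180 for boldine, 3036 for bulbocapnine and 1150 for roemerine. The direction of the fold changes, which the headers leave open, followed from these counts: in all 4 tables, every gene compared had a positive deposited log2 fold change where the count was higher with the alkaloid. On simulated tables of 4332 genes the procedure returned all 5 counts for 99.9% of genes, left 3 undecided and got 0 wrong.

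Total counts were 4806631 in DMSO, 4504247 in berberine, 4796417 in boldine, 4688189 in bulbocapnine and 4849272 in roemerine. Ratios of alkaloid over DMSO were taken after division by the authors' size factors. Their 95% intervals are exact Clopper-Pearson intervals on the 2 counts and cover counting error only. A count of 0 was set to a floor of 3 counts, and no ratio was taken where both libraries were at or under it. Scaling by the total count instead shifts all log2 ratios by 0.46 for berberine, 0.08 for boldine, 0.09 for bulbocapnine and −0.25 for roemerine.

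The test fixed before the data were examined was the authors' adjusted p-value at a threshold of 0.05. It rests on 1 library per condition, so no spread between replicates stands behind the deposited standard errors and p-values. Counts of unadjusted p-values are set beside those of a uniform spread of p-values (an equal share at every size). Without replicates p-values need not be so spread, so such a count neither shows nor excludes changed genes. Differences between 2 alkaloids were tested with a two-sided Wald test on the deposited log2 fold changes and standard errors, with Benjamini-Hochberg adjustment. It was tried on simulated fold changes with 1 known error for all genes, no shrinkage towards 0 and no shared control. There this test found 41% of 100 genes per size changed by 2 on the log2 scale and 98% of those changed by 4, and called 9 unchanged genes. The deposited values differ from that setting, so these shares do not give the power of the test here. A further 48 gene lists (1080 entries, 979 measured) were fixed before the data were examined. For each, the median deposited log2 fold change was set among 10000 random lists matched on the mean normalized count of the 2 libraries compared. That mean includes the alkaloid library itself, so lists were not matched on abundance in the other libraries. A list outside the central 95% of its random lists is described as standing apart. Of 48 lists of genes drawn independently, about 2.4 would do so. Members of a list can vary together, so more lists could stand apart with no effect of an alkaloid. These percentiles describe the libraries and are not p-values.

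The rule for named genes took the 8 highest and 8 lowest per alkaloid past the adjusted p threshold, 3 members per list, 5 genes per direction for all 4 alkaloids and 4 per direction for each pair. It named 0 genes. The same rule without the threshold, the 8 highest and 8 lowest by count ratio, and a size rule of at least 4-fold at a mean normalized count of at least 50 were used in its place. These were chosen after the data were seen, and so were the few genes named beside them. Alternatives covered thresholds, minimum counts, centring, the scaling of the libraries, rank correlation and the error of differences. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and Matplotlib 3.10.9 for plots.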

Results

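The transcriptome of *B. subtilis* 168 was compared between cultures given 75 mg/L of an alkaloid for 1 h and a culture given DMSO. The series asks how these alkaloids act on bacteria. Boldine, bulbocapnine and roemerine are aporphines that differ in the groups on their aromatic rings, and berberine is a quaternary protoberberine. The dose was matched by mass, not by mole. Each of the 5 conditions had 1 library, with total counts between 4504247 and 4849272, so no difference below has a replicate check. Folds are ratios of normalized counts with 95% counting intervals, and gene lists are described by the median of their members' ratios. By the median deposited log2 fold change, 21 of the 48 lists stood apart from random lists with berberine, 13 with boldine, 20 with bulbocapnine and 16 with roemerine. By the median count ratio 22, 15, 21 and 16 did. Lists of genes drawn independently would give about 2.4, but members of a list can vary together, also between cultures with no alkaloid effect.

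Roemerine, an aporphine with a methylenedioxy bridge and an unsubstituted second aromatic ring, went with the highest median ratio of iron acquisition genes among the 4 alkaloids. Of the 32 measured members of the Fur list (genes repressed when iron is plentiful), 29 were at least 2-fold higher than in DMSO and 0 were at least 2-fold lower, with a median log2 ratio of 5.20. The *dhb* genes, which make the siderophore bacillibactin, had the highest counts in the list, while *ykuO* (2705 counts against 2) and *ykuP* (1473 against 1) had higher ratios, with counting intervals that overlap those of the *dhb* genes. *dhbC* had 29340 counts against 30 in DMSO, and *dhbF* had 143660 against 339, a ratio of 500 (449 to 558). Together the 5 *dhb* genes took 4.91% of all counts in the roemerine library and 0.00901% in the DMSO library. *besA*, whose product releases iron from bacillibactin, had 6078 counts against 8, and the ferrichrome transport gene *fhuC* was 64.0-fold higher (42.0 to 102).

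Oxygen limitation genes were lower with roemerine. Of 18 measured, 13 were at least 2-fold lower and 0 were higher by that much, with a median log2 ratio of −4.56. The nitrate reductase gene *narG* had 169 counts against 58837, and *narH* had 21 against 25074. *alsS*, the first gene of acetoin synthesis, had 48 counts against 7300. *cydD*, needed to assemble cytochrome bd oxidase, was 47.9-fold lower (38.6 to 60.03). Pyrimidine synthesis genes were lower as well, 8 of 9 by at least 2-fold, with a median log2 ratio of −5.48. *pyrE* had 22 counts against 3442 and *pyrD* had 21 against 1941. Purine synthesis genes had a median of −1.97, with 13 of 17 at least 2-fold lower. *guaC*, which turns GMP back towards IMP, was 7.77-fold higher (6.55 to 9.26). Branched-chain amino acid synthesis had a median of −2.45, with 7 of 9 at least 2-fold lower, and *leuB* was 9.46-fold lower (6.54 to 14.1). In the sulfur amino acid list 11 of 24 measured members were at least 2-fold lower, with *cysC* at 12 counts against 95.

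Several stress groups had higher counts with roemerine. In the SigB general stress list 27 of 41 members were at least 2-fold higher and 0 lower, with a median log2 ratio of 2.13, and *csbC* was 19.8-fold higher (15.9 to 24.996). In the SOS list, 16 of 24 were at least 2-fold higher and 0 lower, with a median of 1.29. Of its members, *dinB* was 8.74-fold higher (7.25 to 10.6), *lexA* 3.41-fold (3.21 to 3.62) and *recA* 2.48-fold (2.38 to 2.59). The cell envelope genes *liaI* and *liaH*, which respond to antibiotics that act on the cell wall, had 1276 counts against 23 and 3672 against 68. The envelope stress list as a whole did not stand apart. The inositol genes *iolH* and *iolG* were 47.4-fold (42.0 to 53.7) and 34.6-fold (31.0 to 38.8) higher. The peptide transport list had a median of 1.26, with *oppA* at 24752 counts against 5414, and 6 of the 12 measured members of the fatty acid degradation list were at least 2-fold higher. In the osmoprotection list *opuBD* was 45.2-fold higher (20.5 to 124), with 9 of 21 members at least 2-fold higher and 6 lower, but the list no longer stood apart from random lists of all genes or at a minimum count of 50. Secondary metabolite genes were lower, 21 of 41 by at least 2-fold and 0 higher.

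By size, 152 genes were at least 4-fold higher and 81 at least 4-fold lower with roemerine among 2840 at a mean of at least 50, and scaling by total counts made this 130 and 110. In the authors' deposited table for roemerine 0 genes had a DESeq2 adjusted p under 0.05. An unadjusted p under it was given for 122 genes, where a uniform spread of p-values would give 210. Adjusted over the list alone, the p-values of the authors' deposited table gave 21 calls in the Fur list and 8 in the pyrimidine list, against 0 over all genes.

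**Figure D1:**
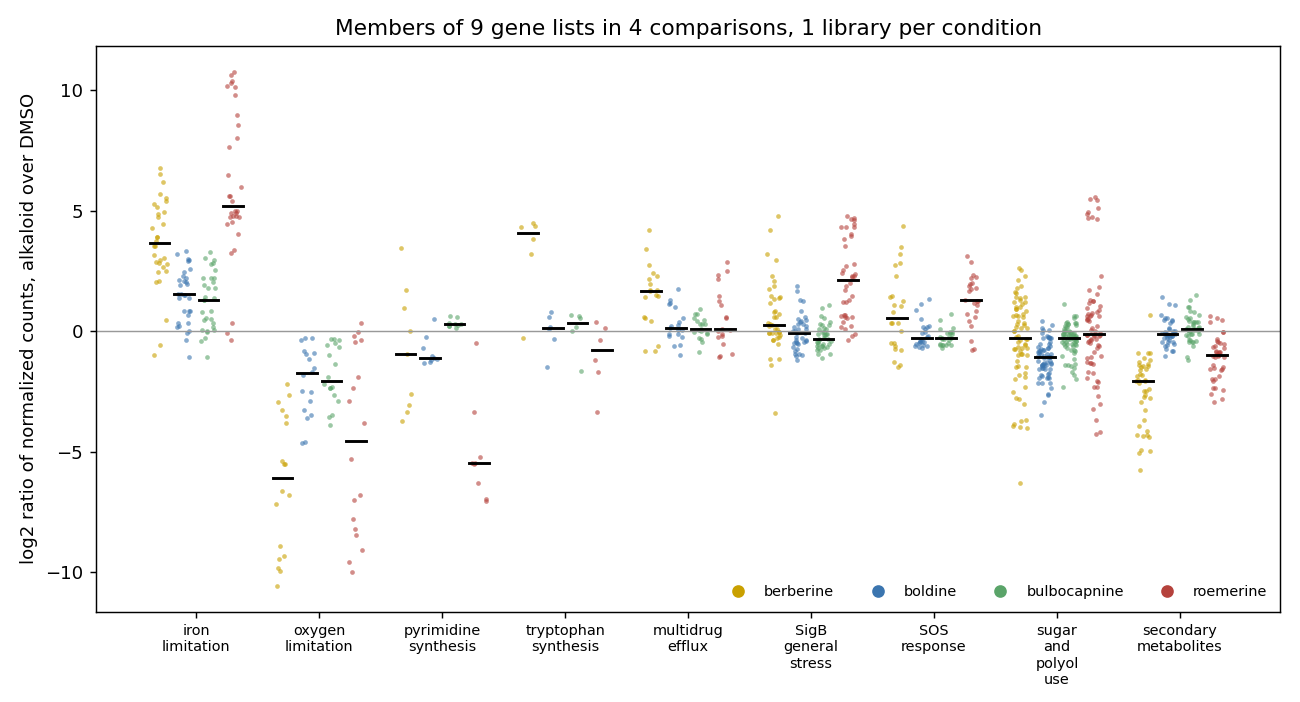
Log2 ratio of normalized counts, alkaloid over DMSO, on the vertical axis for each member (points) of 9 gene lists, with the list median (black bar), for berberine, boldine, bulbocapnine and roemerine. The iron limitation medians are 3.65, 1.52, 1.28 and 5.20, and those of the oxygen limitation list are −6.08, −1.75, −2.04 and −4.56.

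Berberine went with the lowest median ratio of oxygen limitation genes among the 4 alkaloids. All 18 measured members were at least 2-fold lower, with a median log2 ratio of −6.08. *narG* had 84 counts against 58837, a ratio 904-fold lower (730 to 1133). *narI* had 26 against 19549, the regulatory gene *fnr* had 102 against 11494, and *arfM* had 6 against 7018. Respiratory chain genes had a median of −2.21, with 15 of 18 at least 2-fold lower and 2 higher. The cytochrome bd gene *cydA* had 49 counts against 10291, and *qoxB*, of the main quinol oxidase, was 4.67-fold lower (4.57 to 4.78). In the tricarboxylic acid cycle 9 of 11 genes were at least 2-fold lower, with *sucC* at 4.91-fold (4.71 to 5.11), and in glycolysis, a list that no longer stood apart on the mean, 10 of 16 were. *gapB*, the dehydrogenase gene of gluconeogenesis, was 15.7-fold higher (12.9 to 19.4). Branched-chain amino acid genes had a median of −2.49, with 8 of 9 at least 2-fold lower and *ilvB* 10.1-fold lower (8.23 to 12.5). Purine genes had a median of −1.71, with 11 of 17 at least 2-fold lower. Of 41 secondary metabolite genes 37 were at least 2-fold lower and 0 higher. *albA*, of subtilosin maturation, was 33.4-fold lower (30.2 to 37.0) and the surfactin gene *srfAA* 4.37-fold lower (4.07 to 4.69).

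Iron acquisition genes were higher with berberine, 29 of 32 by at least 2-fold and 0 lower, with a median log2 ratio of 3.65. *besA* had 1122 counts against 8, *dhbC* was 41.9-fold higher (29.3 to 62.4) and the bacillibactin import gene *feuB* 30.8-fold higher (20.6 to 48.3). The 6 tryptophan synthesis genes had a median of 4.07, with 5 at least 2-fold higher. *trpB* had 489 counts against 19 and *trpC* had 176 against 6. The other gene, *trpA*, had 1321 counts against 1236 and was the only one with more than 54 in DMSO. In the multidrug efflux list 13 of 19 genes were at least 2-fold higher and 0 lower, with a median of 1.68. The efflux gene *lmrB* was 10.7-fold higher (8.82 to 13.2) and its repressor gene *lmrA* 18.1-fold higher (12.6 to 27.0). In the cell envelope stress list 16 of 41 were at least 2-fold higher and 0 lower. *sigW*, the sigma factor of this response, had 13575 counts against 1195, and the gene of its antagonist, *rsiW*, had 14829 against 1733. In osmoprotection 11 of 21 genes were at least 2-fold higher and 0 lower, with the choline uptake gene *opuBA* at 269 counts against 5. In the SOS list, 11 of 24 were at least 2-fold higher and 3 lower, with *uvrX* at 105 counts against 4, but the list did not stand apart from random lists of all genes. The zinc limitation list had a median of 2.44, ribosomal proteins 0.66 and the PBSX prophage 0.67. Of the genes outside the lists, *yaaH* had 4211 counts against 34 and *yvdQ* had 661 against 6.

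By size, 278 genes were at least 4-fold higher and 178 at least 4-fold lower with berberine among 3090. Scaling by total counts made this 396 and 105, and a minimum mean of 200 made it 129 and 149. Ratios in berberine also went with abundance, with a median log2 ratio of 1.22 for genes with a mean of 5 to 10 counts in the other libraries and −0.96 above 3000. In the authors' deposited table for berberine 0 genes had a DESeq2 adjusted p under 0.05. An adjusted p was given for 464 genes only, all with a mean normalized count of at least 2062, and the smallest was 0.0962. The 9 genes below 0.1 (*cydA*, *narJ*, *fnr*, *narK*, *narH*, *nasD*, *narG*, *narI* and *ywiC*) were all lower. Scarcer genes had no adjusted p and could not be among the 9, such as *yaaH* and *besA*, which were higher. At an unadjusted p under 0.05 that table held 217 genes, where a uniform spread of p-values would give 213. Adjusted over the list alone, it gave 15 calls in the oxygen limitation list, 13 in the Fur list, 6 in osmoprotection, 4 in tryptophan synthesis, 3 in the respiratory chain and 1 (*gapB*) in gluconeogenesis, against 0 over all genes.

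**Figure D2:**
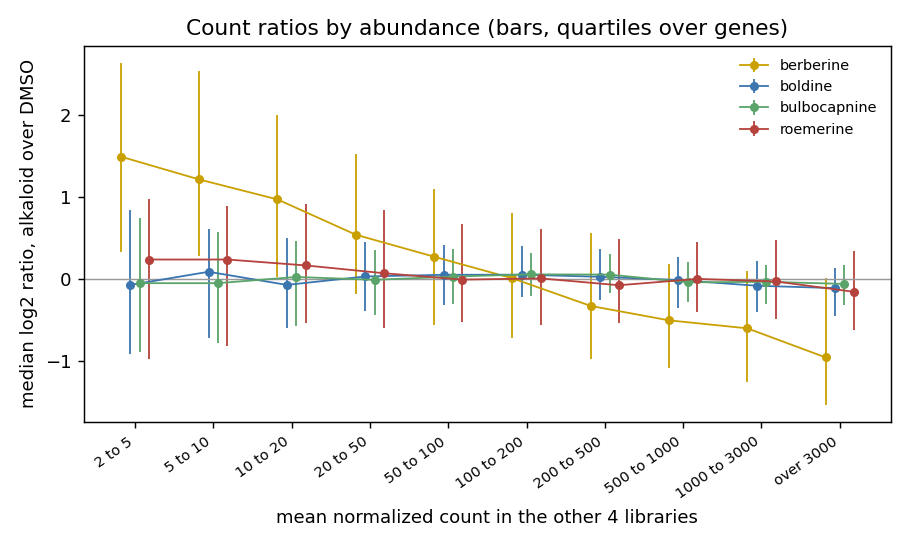
Median log2 ratio of counts, alkaloid over DMSO (points, with quartiles over genes as bars), in bins of the mean normalized count in the 4 libraries other than the one tested. Berberine runs from high to low across the bins, −0.96 in the last, and its bin medians span 2.46, against 0.20 in boldine, 0.12 in bulbocapnine and 0.39 in roemerine.

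**Figure D3:**
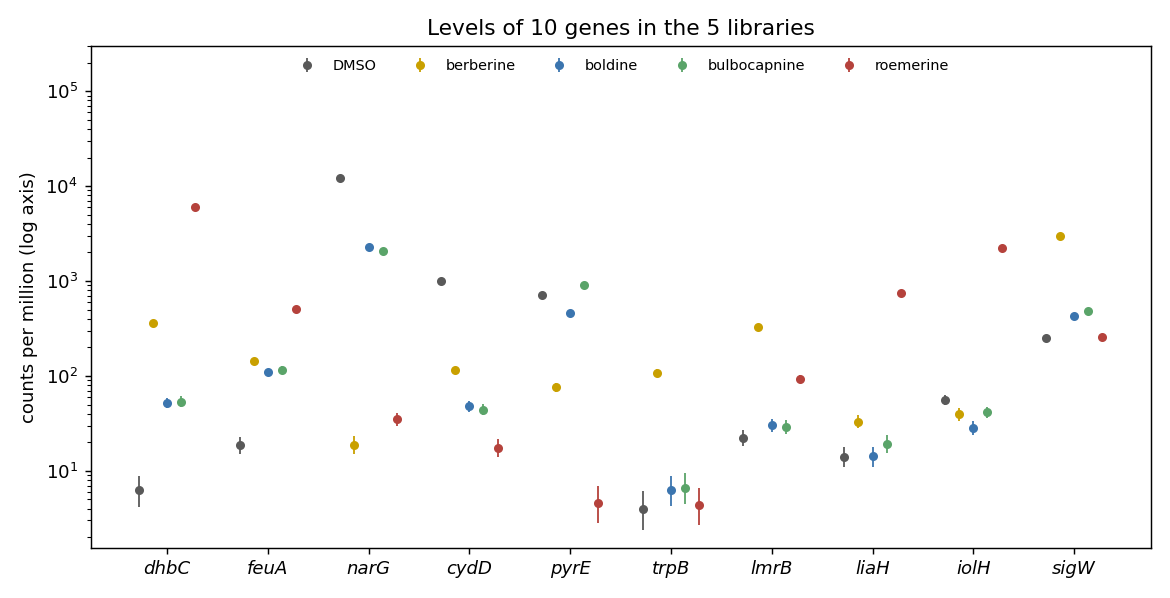
Counts scaled to a common library total (CPM) on a log axis for 10 genes in the DMSO, berberine, boldine, bulbocapnine and roemerine libraries (points, 1 library each), with 95% Poisson intervals of the count as bars. The dhbC counts behind the points are 30, 1623, 251, 252 and 29340, and those of narG are 58837, 84, 10894, 9627 and 169.

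Boldine, with hydroxy and methoxy groups on both aromatic rings, went with smaller ratios. Oxygen limitation genes had a median log2 ratio of −1.75, with 12 of 18 at least 2-fold lower and 0 higher. *alsS* had 306 counts against 7300, *narI* was 12.2-fold lower (11.6 to 12.8) and *narG* 5.68-fold lower (5.56 to 5.80). *cydD* was 21.8-fold lower (19.1 to 25.03). Iron acquisition genes had a median of 1.52, with 20 of 32 at least 2-fold higher and 1 lower. *dhbF* was 9.08-fold higher (8.12 to 10.2), *dhbC* 7.96-fold (5.44 to 12.04) and *feuA* 5.56-fold (4.44 to 7.03). In the list of catabolite-repressed sugar and polyol genes 40 of the 72 measured members were at least 2-fold lower and 0 higher. The mannitol gene *mtlD* was 11.1-fold lower (9.81 to 12.6), the ribose gene *rbsD* 4.44-fold lower (3.54 to 5.63) and *licH*, for use of beta-glucosides, 3.85-fold lower (3.51 to 4.22). The arginine and ornithine use list was higher by a median of 2.84-fold (not log2), with *rocA* at 1540 counts against 175 and *rocD* at 1494 against 388. Pyrimidine genes had a median of −1.09, with 6 of 9 at least 2-fold lower. Flagellar and chemotaxis genes had a median of 0.48, with *cheV* 2.90-fold higher (2.504 to 3.37). The purine list had a median of −0.61 with 0 of 17 members 2-fold apart. In all, 17 genes were at least 4-fold higher and 22 lower among 2847, which became 6 and 20 at a minimum mean of 200 and 10 and 19 with the whole counting interval beyond 4-fold. In the authors' deposited table for boldine 0 genes had a DESeq2 adjusted p under 0.05, and 0 calls were made adjusted over the list alone. An unadjusted p under 0.05 was given for 74 genes, where a uniform spread of p-values would give 210.

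Bulbocapnine, with a methylenedioxy bridge on one aromatic ring and hydroxy and methoxy groups on the other, had the fewest genes apart from DMSO, 11 at least 4-fold higher and 15 lower among 2850, which became 6 and 15 at a minimum mean of 200 and 6 and 13 with the whole counting interval beyond 4-fold. Oxygen limitation genes had a median log2 ratio of −2.04, with 11 of 18 at least 2-fold lower and 0 higher. *narI* was 14.9-fold lower (14.1 to 15.8), *narG* 6.33-fold (6.20 to 6.47) and *cydD* 24.0-fold (20.9 to 27.7). Iron acquisition genes had a median of 1.28, with 17 of the 32 measured at least 2-fold higher and 1 lower. *dhbC* was 8.11-fold higher (5.54 to 12.3), *dhbF* 7.16-fold (6.39 to 8.05) and *yfiY* 4.57-fold (3.32 to 6.43). Among the sugar and polyol genes 11 of 72 were at least 2-fold lower and 1 higher, with *mtlF* at 126 counts against 479 and *mtlA* at 731 against 2282. Biofilm matrix genes had a median of 0.63, with *sipW* at 79 counts against 29, and flagellar genes one of 0.42, with *cheV* 2.31-fold higher (1.98 to 2.70). The cell wall protease gene *wprA* was 2.47-fold higher (2.42 to 2.53). PBSX prophage genes had a median of −0.53, with *xlyA* at 669 counts against 1248. The heat shock list had a median of −0.40, with *radA* 2.53-fold lower (2.31 to 2.76) and *ctsR* 2.23-fold lower (1.79 to 2.79). In the authors' deposited table for bulbocapnine 0 genes had a DESeq2 adjusted p under 0.05, and 0 calls were made adjusted over the list alone. An unadjusted p under 0.05 was given for 61 genes, where a uniform spread of p-values would give 210.

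Across the 4 alkaloids, 25 genes were at least 2-fold higher and 21 at least 2-fold lower in every comparison among 2957. The 4 comparisons share the DMSO library, so a gene out of place in that library alone would count here too. The higher ones included *dhbA*, *dhbB*, *dhbC*, *dhbE*, *dhbF*, *besA*, *feuA*, *feuB*, *feuC*, *fhuD* and *yusV*. The lower ones included *narG*, *narH*, *narI*, *narJ*, *narK*, *arfM*, *fnr*, *alsS*, *alsD*, the 4 genes *cydA* to *cydD* and the mannitol genes *mtlA*, *mtlF* and *mtlD*. Berberine and roemerine shared 67 genes at least 4-fold higher and 54 lower, where independent lists, with no allowance for the common control, would share 9.82 and 4.79. Across genes, which are not replicates, the log2 fold changes of the authors' deposited tables correlated with r = 0.67 between boldine and bulbocapnine. They correlated with r = 0.40 between berberine and roemerine and r = 0.13 between bulbocapnine and roemerine. On count ratios r was 0.75, 0.52 and 0.31 for these pairs. The common DMSO library alone gave about 0.49 to 0.50 in simulation. Unchanged libraries of like spread around 1 control give about that by construction. The SD of the log2 count ratio was 1.63 with berberine, 0.64 with boldine, 0.52 with bulbocapnine and 1.46 with roemerine. An r below the simulated one is therefore no sign of a smaller shared part. On the count ratios the covariance was 0.258 for boldine with bulbocapnine, 1.13 for berberine with roemerine and 0.232 for bulbocapnine with roemerine, against 0.0884 simulated with the spread between boldine and bulbocapnine. The covariance of the deposited fold changes lay below its simulated value in all 6 pairs, at 0.0528 against 0.0677, 0.308 against 0.442 and 0.0229 against 0.130 for the same pairs. That simulation took the deposited errors as noise alone. Without replicates those errors can hold the difference between alkaloid and DMSO, so it cannot decide whether there is an excess. The share of the common control cannot be split off.

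Between the alkaloids, where the control cancels, boldine and bulbocapnine lay closest. Their log2 ratio had an SD of 0.42 across genes, and 3 genes were at least 4-fold apart, all higher with bulbocapnine: *alsS* (1475 counts against 306), *alsD* (1014 against 216) and *licB* (194 against 49). The pyrimidine genes had a median log2 ratio of −1.29 (quartiles −1.47 to −0.97) for boldine over bulbocapnine, and the betaine uptake gene *opuAA* had 1852 counts with boldine against 472. The deposited log2 fold changes of *opuAA* differed by 1.31 (95% interval 0.22 to 2.41) between the authors' deposited tables, which did not pass the Wald test with Benjamini-Hochberg adjustment.

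Roemerine stood farther from both other aporphines. It had 168 genes at least 4-fold above boldine and 86 below, and 156 above bulbocapnine and 86 below. Scaling by total counts made this 125 and 140, and 129 and 146. Bulbocapnine over roemerine had a median log2 ratio of −4.54 in Fur genes (quartiles −6.93 to −3.14), 5.76 in pyrimidine genes (5.41 to 6.57), 3.60 in oxygen limitation genes (0.25 to 5.36) and −2.34 in SigB genes (−3.65 to −1.21). *iolD* had 10368 counts with roemerine, 181 with boldine and 274 with bulbocapnine. Berberine and roemerine differed too, with 211 genes at least 4-fold higher in berberine and 230 in roemerine, which became 409 and 94 under scaling by total counts. The 9 pyrimidine genes were all at least 4-fold higher with berberine than with roemerine, and 5 of the 6 tryptophan genes were. The ribosome-associated gene *yvyD* had 1744 counts with berberine and 75908 with roemerine. In each of the 6 pairs 0 genes passed the Wald test of the difference with Benjamini-Hochberg adjustment over all genes. Adjusted over the list alone, some oxygen limitation genes passed for berberine with boldine and with bulbocapnine. So did some tryptophan genes for berberine with bulbocapnine, sugar and polyol genes for boldine with roemerine and pyrimidine genes for bulbocapnine with roemerine. The genes at an unadjusted p under 0.05 were fewer in every pair than the 209 to 210 of a uniform spread of p-values. They numbered 136 for berberine with boldine, 166 with bulbocapnine and 65 with roemerine. For boldine with roemerine there were 63, for bulbocapnine with roemerine 96 and for boldine with bulbocapnine 7. The test uses deposited values, which are compressed unequally between tables, so neither a pass nor a failure need reflect the counts. For berberine with roemerine 9 of the 65 genes (*besA*, *dhbA*, *dhbB*, *dhbC*, *dhbE*, *narH*, *narJ*, *ykuO* and *ykuP*) had counts in the opposite order, and 385 genes at least 4-fold apart by counts did not reach that p. With the error lowered for a control that carries as much variance as each alkaloid library, 35 genes passed for berberine with boldine, 52 for berberine with bulbocapnine and 10 for boldine with roemerine, the last being *iolB* to *iolJ* and *mmsA*. Of these, *alsD* and *alsS* with boldine and *cydC* with bulbocapnine lay within 2-fold of berberine by counts.

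Among genes at least 4-fold apart, the Spearman correlation between the size of the fold change in the authors' deposited table and that of the count ratio was 0.98 for berberine, 0.69 for roemerine, −0.77 for boldine and −0.85 for bulbocapnine. In the authors' deposited table for roemerine *dhbC* was listed at a log2 fold change of 0.44 and *iolH* at 2.46, with count ratios of 1154 and 47.4. In the authors' deposited table for bulbocapnine *narG* was listed at −0.25 and *mtlF*, which was 3.94-fold lower, is among the 8 lowest.

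**Figure D4:**
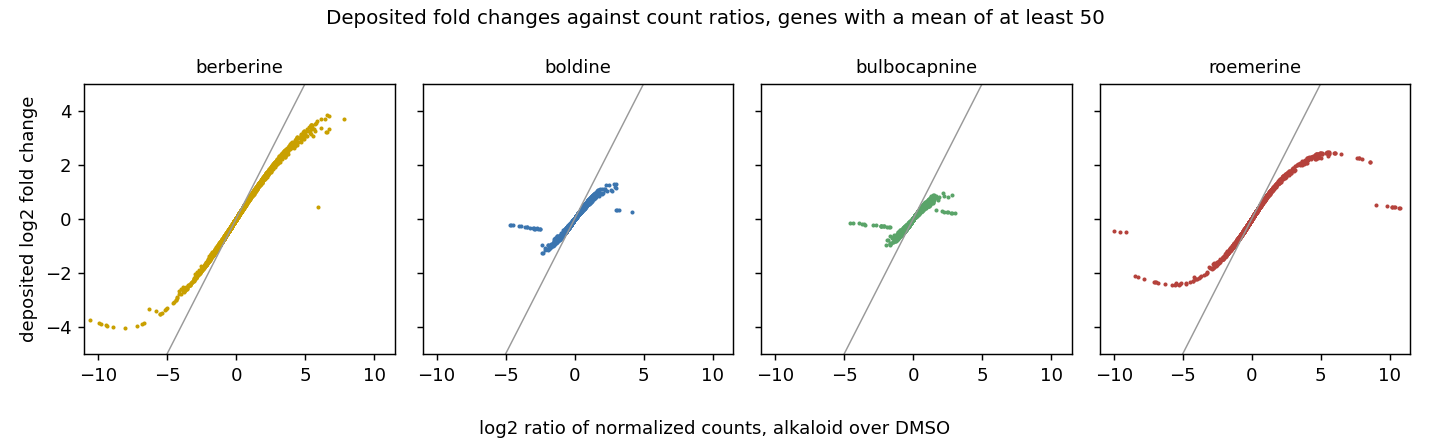
Log2 fold change in the authors' deposited tables (vertical axis) against the log2 ratio of normalized counts (horizontal axis), 1 point per gene with a mean of at least 50, for berberine, boldine, bulbocapnine and roemerine, with the line of equality in grey. In boldine and bulbocapnine the points bend back towards 0 at large count ratios, as some do in roemerine, where dhbC lies at a count log2 ratio of 10.17 and a deposited value of 0.44.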

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

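The scaling by total counts, the other scalings and minimum counts of the size rule, and the count ratios in the correlations and in the lists were chosen after the data were seen; the other settings were planned. The count of 0 called genes per alkaloid held under a minimum mean count, adjustment over every gene and centring (a threshold of 0.01 and a minimum fold change can only lower a count, so they test nothing here), and a threshold of 0.1 called 9 genes in berberine, since it lies above their adjusted p. Of the 70 list medians that stood apart, scaling by total counts and centring changed the sign of 0. Only the sign was checked there, as both shift all genes alike, so neither could end a list standing apart. With the mean in place of the median 5 lists no longer stood apart (flagella, glycolysis, gluconeogenesis and peptide transport in berberine, gluconeogenesis in bulbocapnine) and ribosomal proteins in bulbocapnine turned to −0.013. Random lists from all genes ended 6 (SOS, gluconeogenesis, translation factors and peptide transport in berberine, ribosomal proteins and osmoprotection in roemerine), and so did a minimum count of 50 (arginine use and peptide transport in berberine, osmoprotection and peptide transport in boldine, arginine synthesis and osmoprotection in roemerine). Count ratios ended 1, peptide transport in boldine. With the error of differences lowered for the shared control, 35 genes passed for berberine and boldine, 52 for berberine and bulbocapnine and 10 for boldine and roemerine, by construction of the smaller error. On count ratios the correlations were 0.37 for berberine and bulbocapnine, 0.52 for berberine and roemerine, 0.37 for boldine and roemerine and 0.31 for bulbocapnine and roemerine; the cause was not tested. Genes at least 4-fold lower with berberine numbered 105 under scaling by total counts and 102 with scaling on genes with a mean of at least 500, since both raise every ratio. A minimum mean of 10 gave 433 genes at least 4-fold higher and 200 lower in berberine, 27 and 26 in boldine and 17 and 17 in bulbocapnine; one of 200 gave 129 and 149, 6 and 20, and 6 and 15, so in berberine more genes were then lower than higher. Requiring the whole counting interval beyond 4-fold left 10 genes higher in boldine and 6 in bulbocapnine. Between alkaloids, scaling by total counts gave 409 genes at least 4-fold higher in berberine than in roemerine and 94 the other way, and 140 higher in boldine and 146 in bulbocapnine than in roemerine. A minimum of 200 left 94, 99 and 94 genes higher in berberine than in boldine, bulbocapnine and roemerine. The correlation over genes not called is the same as over all genes, as 0 were called. Count-based tests and leaving out replicates were not run, because each condition has 1 library. No paired analysis was possible because each group has 1 sample.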

Other observations

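Further genes were named after their values were seen. The glycogen genes had higher counts with berberine than in the 4 other libraries: *glgA* had 847 against 12 in DMSO and 23 with roemerine, *glgD* 463 against 12 in DMSO, and *glgP* 976 against 37 in DMSO. *yvdR* and *yvdS* had 1340 and 1412 counts with berberine and 24 and 19 in DMSO. *mrgA*, a gene of the peroxide response, had 9018 counts with berberine against 577, while *ahpC*, of the same response, had 9119 against 12260. With roemerine *ahpC* had 33413 counts and *mrgA* 1036. The 9 genes *iolB* to *iolJ* had between 2626 and 10733 counts with roemerine, while *iolG* had 265 with berberine, 161 with boldine and 226 with bulbocapnine.

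Some genes had higher counts than in DMSO with boldine, or with both boldine and bulbocapnine. *wapA*, a gene of a cell wall-associated toxin, had 44861 counts with boldine and 51851 with bulbocapnine, against 16060 in DMSO, 11652 with berberine and 11195 with roemerine. *yolJ*, of the SPβ prophage, had 20859 counts with boldine, 12711 with bulbocapnine and 1670 with roemerine, against 6488 in DMSO. The cold shock gene *cspD* had 73446 counts with boldine against 40306 in DMSO and 36286 with bulbocapnine.

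The tests below were chosen after the result was seen, apart from that of the prior width, which was set before its values were seen but after 2 other tests of the same pattern had not decided. The deposited log2 fold changes shrink for the genes farthest apart: over genes at least 16-fold apart the median gene kept 46.7% of its count log2 ratio in roemerine, 63.4% in berberine, 5.42% in boldine and 3.41% in bulbocapnine, against 75.1%, 79.0%, 63.0% and 55.9% for genes 2- to 4-fold apart. Only 5 genes in boldine and 2 in bulbocapnine lay at least 16-fold apart. Wrongly recovered counts would in general not give 1 DMSO count shared by the 4 tables, and 4332 of 4332 genes had one. The recovery itself required such a count, so this is not a separate check of it. A candidate explanation is shrinkage by 1 prior per table, stronger for genes whose dispersion was estimated as larger because their 2 libraries differ; the prior width implied by count ratio, deposited fold change and error would then be equal for all genes, and its 95th percentile was at most 1.10 times its 5th in the 4 tables. The 2 earlier tests left it open. The median deposited value was smaller for genes over 16-fold apart than for genes 4- to 16-fold apart in 2 of the 4 tables, those of boldine and bulbocapnine with so few such genes. As shrinkage lowers the errors too, 11 of 39 genes at least 4-fold apart in boldine and 0 of 26 in bulbocapnine had an error in the top 2.5% of genes of like abundance. No biological explanation was tested.

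Fur genes were higher and oxygen limitation genes lower in all 4 alkaloid libraries, which share 1 DMSO library. An atypical DMSO library as the whole cause is excluded for berberine and roemerine, because the Fur genes also lay above those of boldine and bulbocapnine, by a median of at least 2.36 on the log2 scale, and the oxygen genes below, by −2.30 at the least (2.75 and −2.62 under scaling by total counts). For boldine and bulbocapnine it cannot be told apart from the alkaloids: their Fur genes differed by a median of 0.27 and no second DMSO library stands beside them. A single state of the culture that differs only in degree, which would keep the order of the libraries, stays open: berberine over roemerine was −2.03 in Fur genes (roemerine farther from DMSO) and −1.62 in oxygen limitation genes (berberine farther), but −1.32 and −0.91 under scaling by total counts, where the upper quartile of the oxygen genes was 0.10. An effect of the alkaloids, which the design names, and a difference between cultures stay open as well, untested with 1 library per condition.

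In berberine, scarce transcripts were higher and abundant ones lower: the median log2 ratio was 1.22 for genes with a mean of 5 to 10 counts in the 4 other libraries and −0.96 above 3000. Its bin medians, from 2 counts up, spanned 2.46, against 0.39 in roemerine, 0.20 in boldine and 0.12 in bulbocapnine. A single scaling factor moves all bins alike and leaves the span as it is. An equal number of background reads in each gene would give equal excess counts over DMSO counts scaled to the genes above 3000. The median excess so taken differed 8.59-fold between bins below 200. The outcome depends on that scale and no other was tried, so equal background reads are not excluded. Background in proportion to gene length was not tested, as no lengths of the authors' build were at hand, and a broad effect of berberine on transcript levels stays open, untested.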
